A study of Mus musculus with 4 samples.

How the data were processed

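Gene expression was measured in molar teeth that were pulled by hand from 60 Swiss Webster mouse pups aged 1 to 10 days after birth, pooled, and ground before RNA extraction. The pooled RNA of both sexes was labelled with biotin and hybridised to 4 Affymetrix Mouse Genome 430 2.0 arrays, a 1-colour oligonucleotide array on which a probe set of short probes reports a transcript, near its 3′ end. All 4 arrays form 1 group. Replicate numbers were taken from the sample titles, because the free-text description of every array gives replicate 1. The 4 arrays come from the same pool, so every SD below is technical, and p-values measure only this technical spread. Whether the pool was labelled separately for each array is not given in the sources used here, so the spread includes hybridisation and scanning and may or may not include labelling. The study's design sets these arrays against 16 control tissues of another series, which are not analysed here, so no between-tissue comparison was made.

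The deposited table holds 1 signal intensity per probe set and array for 45101 probe sets, on a linear scale. Per the submitters' processing notes, the authors used MAS5, Affymetrix's summary of perfect-match and mismatch probes. Its version, settings and detection calls are not given in the sources used here. The mean signal without the lowest and highest 2% of probe sets was 2500 on each array when computed from the deposited intensity values, so the arrays had been scaled to a common target. MAS5 subtracts a mismatch estimate, which makes low signals noisy, and its linear scaling does not remove differences between arrays that depend on brightness. Depth in the sense of read counts does not exist for arrays, and the number of arrays limits the precision. Signals of different probe sets depend on probe affinity and are not compared as amounts of mRNA.

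Probe sets were named from the platform annotation: 34958 named 1 gene, 932 named several and were not used for genes, and 9160 had no gene name here. Control probe sets numbered 64, of which 13 carry a gene name. The named probe sets covered 18195 genes. Gene IDs of 34754 of the 34958 probe sets matched the reference gene table (GRCm38.p6), which changed no symbol. No genome build is named for the table, so no coordinates are given. A gene was represented by its probe set of highest mean log2 signal.

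Background was estimated, on each array, as the 95th percentile of the signals of 86 probe sets naming olfactory, vomeronasal or taste receptor genes, which are not expected in teeth. A probe set was called above background if its signal exceeded this threshold on all 4 arrays, and a gene if any of its probe sets was. The background rule, 25 gene lists with 484 entries, the rule for named genes and the alternatives were fixed before the data were examined. The exception is the limma trend, which was added after a simulation that drew on these arrays. Of the entries, 437 were measured, 45 had no probe set naming that gene alone here and are not analysed, and 2 repeated another entry. For each list the number of members above background, and the median log2 signal, were set beside 10000 random gene lists of the same size matched on the number of probe sets per gene (1, 2, 3, and 4 or more). The percentile describes where a list stands on these arrays and is not a p-value, because genes are not replicates.

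The text names, per list, the 3 members above background with the highest signal (2 for lists other than the 7 tooth lists) and, for tooth lists, up to 3 members not above background in alphabetical order, the 4 measured sex-linked genes, the 15 genes with the highest signal and the 5 genes above background with the largest SD. Genes named beyond this rule were chosen after their values were seen, namely Dspp, Dmp1, Ibsp, Mmp20, Klk4, Amtn, Odam, Msx1, Pax9, Barx1, Bmp4, Wnt10a, Fgf3, Fgf4, Fgf8, Fgf9, Trp63, Postn, Lor, Krt13, Mylpf, Mki67, Col2a1, Acan, Col10a1, Pecam1, Alb and the family members in the closing section.

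Alternatives were the 99th and 75th percentile of the background set, a background from testis and retina probe sets, a call on at least 3 of the 4 arrays, a one-sided limma test of log2(signal / threshold) with a mean-variance trend and a Benjamini-Hochberg adjusted p under 0.05, quantile normalisation, probe sets without the suffixes that mark shared sequence, the median probe set of a gene, and leaving out each array. The shared-sequence suffixes (_s_at, _x_at and _a_at) mark sequence shared between transcripts, which for _a_at are transcripts of the same gene. The limma trend was added after simulated data had shown that limma without it called no gene. The calls were tested on simulated data in which 200 of 18195 genes were set above the threshold. The all-array rule called 86% of the 50 genes set 1.5-fold above it, 98% at 2-fold, 100% at 4-fold and 100% at 8-fold, and 0.300% of the genes drawn from background. The limma test called 0% at 1.5-fold and at 2-fold, and 100% at 4-fold and at 8-fold. In the simulation 17995 of 18195 genes were drawn from background, unlike on these arrays, so the limma rates do not carry over. On the real arrays limma called Hbb-b2 at 1.51-fold (adjusted p 0.0078) and Pax9 at 1.85-fold (adjusted p 5.7e-05). Simulated background came from the receptor probe sets that set the threshold, so the 0.300% does not test that choice. A list of 20 genes set 8-fold above the threshold had 20 members called, and a list of 20 background genes had 0. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, R 4.3.3, limma 3.58.1 and matplotlib 3.10.9.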

Results

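RNA from 1 pool of mouse molar teeth, collected from 60 pups between 1 and 10 days after birth, was measured on 4 arrays. These days span the laying down of enamel and dentin in the crown. The study's design sets the arrays against control tissues of another series, which are not analysed here. The comparisons open to these 4 arrays are between the arrays and between gene groups and the background. Of 18195 genes, 9392 (51.6%) had a probe set above background on all 4 arrays. The background threshold was 1163 ± 142 signal units (SD, n = 4 arrays), the median signal of an array was 818 ± 61.3, and the highest signal on an array ranged from 156681 to 257968.

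The 15 genes with the highest mean signal included 3 enamel matrix genes, Amelx (amelogenin), Ambn (ameloblastin) and Enam (enamelin), and 3 genes of the collagenous matrix of dentin and bone, Col1a1, Col1a2 and Sparc. Clu (clusterin, a secreted chaperone) had a signal of 206922 ± 42901 (SD, n = 4). Eef1a1, an elongation factor, had 186084 ± 25226, and the ribosomal protein genes Rpl41, Rpl4, Rps3a1 and Rps29 had 190827 ± 36330, 155708 ± 24028, 152558 ± 18006 and 152056 ± 16444. The remaining genes were Tpt1 (180175 ± 28717), Itm2b (160203 ± 25789) and Actb (148924 ± 28811). Brightness also depends on the probe, so this is not an order of mRNA amounts, and with probe sets free of shared-sequence suffixes Rpl41 and Tpt1 were not above background.

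Enamel genes were above background throughout the matrix list. All 8 measured genes for enamel matrix proteins and their proteases passed, against a mean of 3.30 for random lists, and the list's median signal stood at the 100th percentile of random lists. Amelx had a signal of 198666 ± 42644, Ambn 167142 ± 28027 and Enam 141225 ± 13375. Mmp20, the protease of secretory-stage enamel, had 52838 ± 2524, and Klk4, the protease of the maturation stage, had 22627 ± 5808. Odam and Amtn, secreted by maturing ameloblasts, had 49866 ± 3484 and 34128 ± 2621. All of these values lay far above the threshold on each array, with limma adjusted p-values of 1.72e-15 for Amelx, Ambn and Enam.

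Ion transport and other genes of enamel maturation were above background for 11 of 15 measured members, against 6.76 in random lists (percentile 98.8 of random lists). Alpl, a phosphatase needed for mineralisation, had a signal of 52629 ± 3023, the citrate transporter gene Slc13a5 had 25595 ± 1255, and Car2, a carbonic anhydrase, had 18599 ± 1783. The chloride channel gene Cftr had a signal of 1212 ± 212 and exceeded the threshold on 1 array, and Slc24a4, a sodium, potassium and calcium exchanger, had 1170 ± 243 and exceeded it on 2 arrays. Cldn16 had 95.3 ± 20.2 and exceeded it on 0 arrays. The pool is not separated by cell type, so the list does not assign these signals to ameloblasts.

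Genes of dentin and mineralised matrix were above background for 13 of 14 measured members, against 8.33 in random lists (percentile 99.7 of random lists), and the median signal stood at the 100th percentile. Col1a2, Sparc and Col1a1 had signals of 195252 ± 30587, 182924 ± 25344 and 179786 ± 33243. Dspp, which encodes the main non-collagenous proteins of dentin, had 111371 ± 20102. Dmp1 and Ibsp, mineral-binding matrix proteins of dentin and bone, had 27118 ± 3091 and 24189 ± 1339. Mepe had 661 ± 336 and exceeded the threshold on 0 arrays. Most members of this list are also made by bone, so the list does not separate dentin from alveolar bone.

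Transcription factors of tooth development were above background for 20 of 21 measured members, against 11.3 in random lists, a count at the 100th percentile. Sp6 (epiprofin), needed for ameloblast and cusp formation, had a signal of 59832 ± 2728. The homeobox genes Dlx3 and Dlx5 had 23951 ± 1682 and 23012 ± 1459, Msx1 had 9576 ± 1105 and Barx1, a molar-field homeobox gene, had 9540 ± 732. Pax9, active in dental mesenchyme, had 2145 ± 137, and was not above background by the median of its probe sets. Isl1, linked to incisor epithelium, had 191 ± 131 and exceeded the threshold on 0 arrays.

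**Figure D1:**
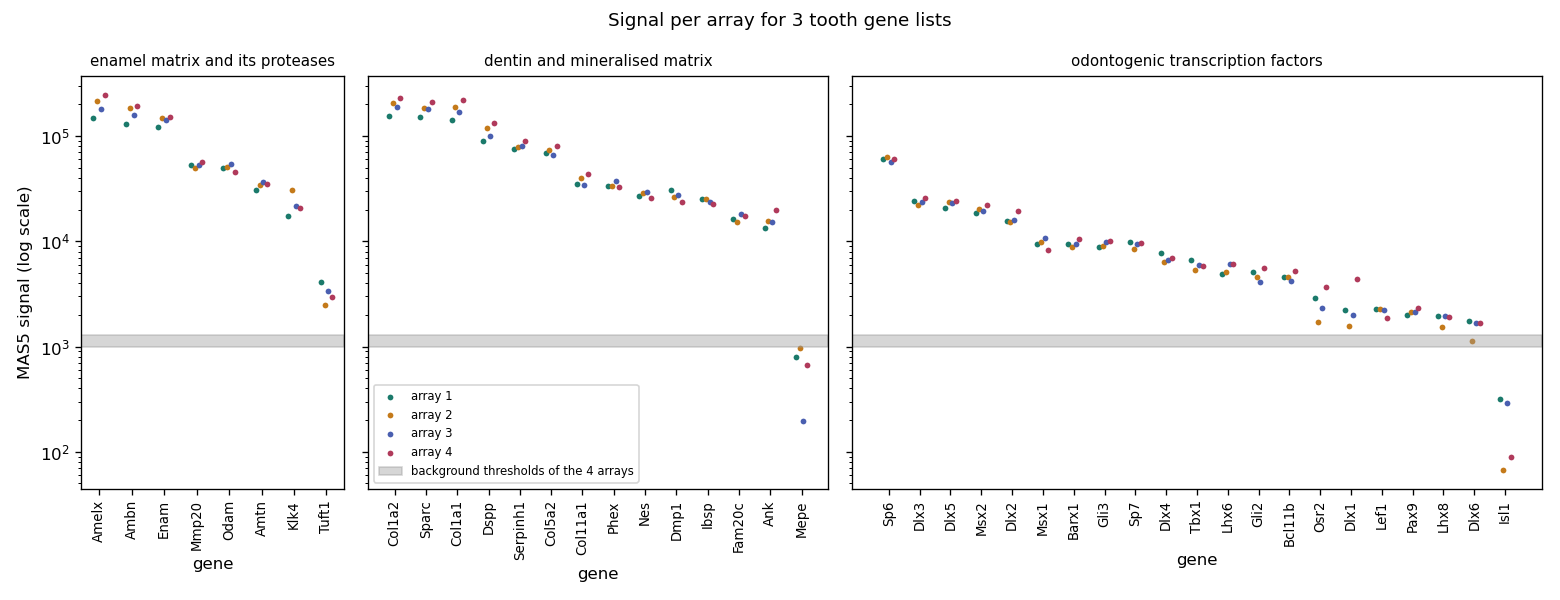
Signal (MAS5 units, log scale) of each gene on each of the 4 arrays, 1 colour per array, for the enamel matrix, dentin and transcription factor lists; the grey band spans the 4 arrays' background thresholds. All 8 enamel genes, 13 of 14 dentin genes and 20 of 21 transcription factors lie above their thresholds on all 4 arrays, while Mepe and Isl1 lie below.

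Signalling genes were mixed. Of 28 measured ligands, receptors and inhibitors, 18 were above background, against 16.4 in random lists (percentile 74.0 of random lists), although the median signal stood at percentile 99.9. Shh had a signal of 64133 ± 8323 and Ptch1, its receptor and target gene, 33079 ± 1775. Sostdc1, a Bmp and Wnt inhibitor, had 29001 ± 1095, Wnt10a 18899 ± 1720 and Bmp4 11384 ± 745. Members not above background included Edar, the ectodysplasin receptor gene, at 233 ± 183 and Edaradd, its adaptor, at 1394 ± 151, which passed on 3 arrays. None of the Fgf genes in the list was above background on all 4 arrays. Fgf9, at 1690 ± 634, passed on 3 arrays and was above background without array 4. Fgf3, at 1138 ± 127, and Fgf4, at 1171 ± 250, passed on 2 arrays each. Fgf10 had 1016 ± 198 and Fgf8 31.7 ± 10.3, and both passed on 0 arrays. A signal not above background does not show that expression was absent.

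Genes of dental epithelium were above background for 19 of 20 members, against 10.6 in random lists (100th percentile). The basal keratin genes Krt5 and Krt14 had signals of 117973 ± 13649 and 84504 ± 6055, the desmosome-associated gene Perp had 64107 ± 3967 and the epithelial transcription factor gene Trp63 had 26758 ± 7197, while Krt19 had 807 ± 326 and passed on 1 array. Dental follicle and periodontal ligament genes were above background for 12 of 13 members, against 6.75 (percentile 99.9 of random lists). The proteoglycan genes Lum and Dcn had 87615 ± 7909 and 84169 ± 12175, Mmp2 had 28460 ± 5762, Postn (periostin) had 25388 ± 1524, and Scx, a tendon and ligament transcription factor gene, had 603 ± 296. These lists do not separate dental from oral epithelium, whose genes Krt4 and Krt13 were also above background, or follicle from other connective tissue.

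Genes of protein secretion and of cell division were above background more often than in random lists. All 28 measured genes of the secretory pathway were above background, against 16.5 in random lists, with P4hb, a subunit of collagen prolyl hydroxylase, at 93592 ± 5585 and the chaperone gene Calr at 72760 ± 6842. Of 25 measured cell cycle genes, 22 were above background, against 14.7 (percentile 99.9 of random lists), with Pcna at 19559 ± 1689, Mcm7 at 13324 ± 371 and Mki67 at 6428 ± 656.

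**Figure D2:**
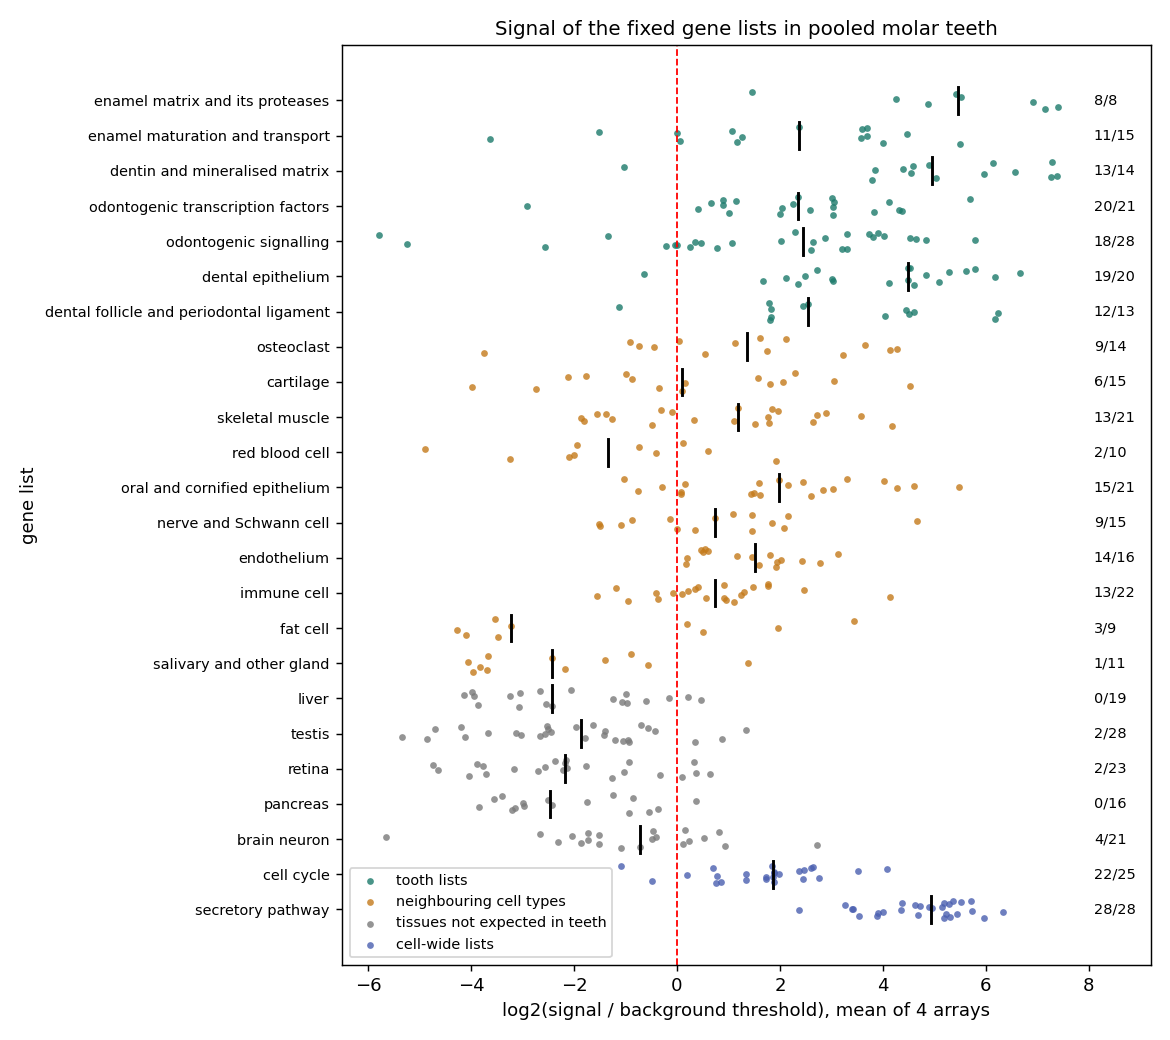
Each point is a gene of a fixed list, placed at the mean over 4 arrays of log2(signal / background threshold); black bars are list medians, the dashed line is the threshold and the figures at the right count the members above background on all 4 arrays. The 7 tooth lists lie mostly to the right of the line, whereas liver and pancreas have 0 of 19 and 0 of 16 members above background.

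Markers of neighbouring cell types differed from list to list. Endothelial genes were above background for 14 of 16 members, against 7.11 in random lists (100th percentile), with Ramp2 at 10168 ± 648, Egfl7 at 7975 ± 377 and Pecam1 at 2587 ± 118. Genes of oral and cornified epithelium were above background for 15 of 21 members, against 9.53 (percentile 99.3 of random lists). They included Krt4 at 52269 ± 6646 and Krt13 at 22666 ± 3358, keratins of the oral lining, Krt6a at 28453 ± 3061, and Lor (loricrin, of cornified cells) at 18867 ± 2922. Skeletal muscle genes were above background for 13 of 21 members, against 9.11 (percentile 95.9 of random lists), with Acta1, the actin of skeletal muscle, at 20889 ± 1385, Myl1 at 13824 ± 2129 and Mylpf at 7617 ± 455. With probe sets free of shared-sequence suffixes, the muscle count was 8 of 16. Acta1 and Myl1, measured only by probe sets with the suffix _a_at, were not tested in that count. The epithelial, connective tissue and muscle values above come from the same pool and are not separated by cell type.

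The osteoclast, immune, nerve, cartilage and fat cell counts lay between percentiles 21.7 and 91.7 of random lists. Osteoclast genes were above background for 9 of 14 members, against 7.21 (percentile 83.6 of random lists), with the bone protease gene Ctsk at 22447 ± 3408 and Csf1r, which is also in the immune list, at 20413 ± 2425. Immune cell genes were above background for 13 of 22 members, against 9.89 (percentile 91.7 of random lists), with Lyz2 at 6475 ± 814. Nerve and Schwann cell genes gave 9 of 15, against 8.11 (percentile 68.1 of random lists), with Pmp22 at 29524 ± 1595 and Stmn2 at 5174 ± 508. Cartilage genes gave 6 of 15, against 7.46 (percentile 21.7 of random lists). With the 75th percentile as threshold the cartilage count was 10. Col11a2 had 26680 ± 3311, Col9a3 9564 ± 969 and Col2a1, the main cartilage collagen gene, 4118 ± 918, while Acan, for aggrecan, had 1238 ± 150 and Col10a1, of hypertrophic cartilage, 75.2 ± 17.4.

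Fat cell genes were above background for 3 of 9 members, against 4.13 (percentile 22.6 of random lists), among them Scd1 at 12584 ± 1807 and Lpl at 4530 ± 519. The median signal of the fat cell list stood lower, at percentile 0.06 of random lists. Red blood cell genes gave 2 of 10, against 4.79 (percentile 3.67 of random lists), Alas2 at 4418 ± 628 and Hbb-b2 at 1781 ± 377. A further 4 probe sets that name a member of this list together with other genes were not used, so the list says little about haemoglobin. Salivary and other gland genes gave 1 of 11, against 4.86 (percentile 0.635 of random lists), namely Kap at 3074 ± 642.

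Genes of tissues not expected in teeth were mostly not above background, at 8 of 107 members (7.48%), compared with 101 of 119 (84.9%) for the 7 tooth lists. With the threshold at the 75th percentile of the background set these counts were 28 of 107 (26.2%) and 109 of 119 (91.6%). Of the 28, 11 were brain neuron genes. Among all 18195 genes, 11878 were above that threshold. At the main threshold the share was 51.6% of all genes. It was 51 of 57 (89.5%) for the secretory, cell cycle and sex-linked lists together, so a high share is not particular to the tooth lists. Liver gave 0 of 19 members, and albumin (Alb) had a signal of 326 ± 254. Pancreas gave 0 of 16. The limma test also called 0 members of each of these lists after adjustment, and 1 member of each at an unadjusted p under 0.05. Testis gave 2 of 28, Tcp11 at 2952 ± 471 and Gapdhs at 2144 ± 395. Retina gave 2 of 23, Crx at 1835 ± 397 and Gnat2 at 1510 ± 183. With the threshold at the 99th percentile of the background set, Crx, Gnat2 and Hbb-b2 were not above background. Brain neuron genes gave 4 of 21, against 12.7 in random lists, with the complexin genes Cplx2 at 7660 ± 935 and Cplx1 at 2292 ± 704.

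The labels give a pool of males and females. Xist, the transcript of the inactive X chromosome, had a signal of 15206 ± 611 and was above background. The measured Y-linked genes were close to the threshold, with Eif2s3y at 1600 ± 623, Kdm5d at 1220 ± 110 and Uty at 938 ± 121, and exceeded it on 3, 3 and 1 of the 4 arrays.

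The arrays agreed closely for bright probe sets and poorly for dim ones. Among the 16133 probe sets above background, Pearson's r of log2 signals across probe sets ranged from 0.970 to 0.980 over the 6 pairs of arrays, and the median SD of log2 signal was 0.17, or 1.12-fold. Over all probe sets r ranged from 0.903 to 0.929. The median SD was 0.99 for probe sets below the 25th percentile of mean signal (median signal 105), 0.28 between the 50th and 75th percentiles and 0.13 between the 90th and 99th. Array 4 had the lowest mean correlation with the others, 0.972 among probe sets above background against 0.975 to 0.977. The 5 genes above background with the largest SD of log2 signal were Rtel1 (1.93), Dpf3 (1.72), Ces5a (1.48), Cklf (1.47) and Fen1 (1.39). For Rtel1, Dpf3 and Cklf the call rests on another probe set of the gene, since the one shown passed on 3 arrays. By the median probe set of a gene, Rtel1, Dpf3, Ces5a and Cklf were not above background. The ratio of 3′ to 5′ signal was 1.16 ± 0.0386 for the beta-actin controls and 0.778 ± 0.0703 for the Gapdh controls (SD, n = 4).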

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

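All tests on array 4 except the one on the secretory pathway list were chosen after its correlations had been seen. A gap test on 162 sets of 4 values picked out 15 in which 1 array lay apart from the other 3, where chance gives about 1 in 20 (8.1 of 162). Array 4 was the one apart in 9 of the 15, against 2 for array 1, 1 for array 2 and 3 for array 3. That rate does not hold for 4 of the 15, which are counts with ties on the other 3 arrays, and 2 more are genes named for their large SD. Without counts and such genes, 9 of 131 sets were picked out against 6.55 by chance, 5 of them on array 4.

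Array 4 stood apart in several ways. Its Gapdh 3′ to 5′ signal ratio was 0.883, against 0.740 to 0.747 on the other arrays, and the median log2 signal of the secretory pathway list was 15.25, against 15.05 to 15.07. Scaling that depends on brightness is a candidate explanation for the secretory list, since its gap of 0.18 above the nearest array became -0.029 after quantile normalisation. It does not account for the array as a whole, whose median absolute deviation among probe sets above background was 0.18 before and 0.16 after quantile normalisation, above the highest of the others both times (0.14 and 0.14). Among probe sets above background its correlation of 0.972 was still below the lowest other value of 0.975 by more than the SD of 0.00105. The lower correlation is thus not confined to probe sets below background. That set includes probe sets just over the threshold, and the other arrays' values include array 4, so noise near background stays open. A stronger 3′ bias stays open, because the beta-actin ratio of 1.17 lay within the range of the other arrays (1.10 to 1.19) while that of Gapdh did not. All arrays carry the same RNA pool, so no biological explanation was tested.

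On single genes array 4 was lower for Krt19 (8.39, others 9.79 to 10.07 on the log2 scale), Stmn2 (12.11, others 12.39 to 12.42), Ces5a (10.78, others 13.60 to 13.90) and Fen1 (10.59, others 13.34 to 13.39), and higher for Mmp2 (15.18, others 14.59 to 14.68). Edar was higher on array 1 (8.99, others 7.03 to 7.32) and Fgf8 on array 3 (5.56, others 4.70 to 4.80), both below the threshold. The median of the odontogenic signalling list was 12.69 on array 3 (others 12.53 to 12.56), and that of the cartilage list 10.45 on array 2 (others 10.12 to 10.16). Counts of members over the threshold of the single array differed by 1 gene: 20 of dental epithelium on array 1 against 19, 2 of red blood cell on array 4 against 3, 1 of liver on array 3 against 2, and 2 of testis on array 4 against 3.

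Probe sets without a gene name here gave signals outside the gene counts: 836 of 9160 (9.13%) were above background on all 4 arrays, against 42.5% of those naming 1 gene.

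Skeletal muscle markers were above background in a pool labelled as teeth. A threshold set too low was tested with the 99th percentile of the background set, 1147 to 1581 over the arrays against 996 to 1295. So small a rise cannot exclude a threshold set too low by more. At the 99th percentile, 57.1% of members stayed above background. The highest share of the liver, testis, retina and pancreas lists was 7.14%, and that of the brain neuron list 19.0%. Of all 18195 genes, 8774 were above the same threshold, so the gap to those lists overstates how muscle stands among all genes. The muscle share stayed at 57.1% without each array in turn. A call needs every array kept, so leaving out an array could not have lowered this share, and it adds no support. Muscle carried along with the teeth and expression by cells of the tooth cannot be told apart, because the share of 61.9% of members above background is the pattern itself.

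Oral and cornified epithelium markers were also above background. At the 99th percentile, 71.4% of members stayed above the threshold, against the same highest share of 7.14% and 19.0% for brain neuron. As for muscle, so small a rise cannot exclude a threshold set too low by more. Among all 18195 genes, 8774 were above that threshold. Gum carried along with the teeth and expression of these genes by dental epithelium cannot be told apart either, because the share of 71.4% above background is the pattern itself.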

How the results depend on the processing

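No paired analysis was possible because the series has 1 group. The count of 9392 genes above background ranged from 7143 (median probe set per gene) to 11878 (75th percentile) over the alternatives, and from 9427 to 9850 with 1 array left out. A call needs every array kept, so leaving out an array can only keep or raise a count. Each of the 7 tooth lists stayed within 1.5 times its count under every alternative, as did the secretory list except with plain probe sets (18 of 19 measured, since fewer genes were tested). Counts that moved further were these. At the 99th percentile, red blood cell fell to 1 and retina to 0. At the 75th percentile, cartilage gave 10, salivary and other gland 2, liver 4, testis 5, retina 5, pancreas 3, brain neuron 11 and the sex-linked genes 4. With a background from testis and retina, red blood cell gave 1. At 3 of 4 arrays, liver gave 2, retina 4, pancreas 1 and the sex-linked genes 3. The limma test gave 1 for retina. With plain probe sets only, skeletal muscle gave 8 of 16, red blood cell 0, salivary and other gland 0 and testis 1. With the median probe set, red blood cell gave 1, salivary and other gland 0 and retina 1. Leaving out an array gave 0 to 1 for liver (1 without array 1 or array 3), 0 to 1 for pancreas (1 without array 4) and 1 to 2 for the sex-linked genes (2 without array 3 or array 4). Beyond the smaller number of genes tested with plain probe sets, the cause was not tested. The median SD of log2 signal of 0.17 became 0.39 over all probe sets, with a lowest r of 0.903, and ranged from 0.14 (without array 4) to 0.17 when an array was left out, with lowest r values of 0.971 to 0.976. Of 104 named genes, 22 changed their call under at least 1 alternative, among them Hbb-b2, Crx, Gnat2, Kap, Pax9, Fgf3, Fgf4, Fgf9, Fgf10, Edaradd, Cftr, Slc24a4 and Acan. Low signals are limited by the noise of dim probe sets, so a member not above background is not shown to lack expression.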

Other observations

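Gene families grouped by symbol were looked at after the fixed lists had been seen, and their members were not chosen beforehand. Collagen genes were broadly present, with 34 of 42 above background against 23.2 in random lists, among them Col3a1 at 116166 signal units and Col4a1, of basement membranes, at 49734. Cathepsins, lysosomal proteases, gave 12 of 22 against 10.9, with Ctsb at 62349 and Ctsl at 33866, and their median signal stood at percentile 99.07 of random lists. Claudins, which form tight junctions, gave 4 of 20 against 8.96, Cldn1 at 23631, Cldn10 at 10305, Cldn12 at 3831 and Cldn5 at 3517. The Fgf family, which includes intracellular members such as Fgf13, gave 2 of 22 against 11.5, Fgf13 at 8660 and Fgf1 at 4071, while Wnt ligands gave 8 of 19 against 9.42 and included Wnt6 at 17507 and Wnt5a at 15452. At the 75th percentile threshold the Fgf count was 11, the claudin count 7 and the matrix metalloproteinase count 12. Among all 18195 genes, 11878 were above that threshold. The family counts thus depend on where the threshold is set.

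Keratins gave 20 of 48 against 19.7, matrix metalloproteinases 7 of 18 against 8.54 with Mmp14 at 29849 and Mmp13 at 8482, and olfactomedin-related genes 5 of 8 against 3.58 with Olfml3 at 22133. Ribosomal protein genes gave 43 of 46 against 24.7, but 14 of 24 with plain probe sets.

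Homeobox genes of the Hox clusters were set beside the Dlx family, which gave 6 of 6 against 2.61 in random lists. At the 99th percentile the Dlx count was 5. All 6 Dlx genes are also in the transcription factor list above, so their count repeats part of that result. The hypothesis, written before the Hox values were seen, was that teeth of the jaw lack most Hox transcripts. Of 33 measured Hox genes, 0 were above background on all 4 arrays, against 14.9 in random lists, a count at the 0th percentile, and the limma test called 0 of them both after adjustment and at an unadjusted p under 0.05. The count was 0 to 1 with an array left out, 0 at the 99th percentile and 4 at the 75th. Hoxc6 had the highest signal, 1203, and passed on 3 arrays. The count of 0 is what the hypothesis predicts, although Hox genes with low expression or weak probe sets could give the same count. The liver, pancreas, testis and brain neuron lists and the Fgf family also had counts at the 0th percentile. That rank is thus not particular to Hox genes.

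Probe sets lost on a single array were rare: of 6714 probe sets over 4 times the threshold on arrays 1 to 3, 4 were at least 4-fold lower on array 4, of which 3 carried a shared-sequence suffix, and 0 were found for arrays 1, 2 and 3. Ces5a and Fen1 had such values, 1762 on array 4 against 12431, 15242 and 13088 for Ces5a, and 1545 against 10527, 10355 and 10762 for Fen1. In the other direction, 2 probe sets were at least 4-fold higher on array 4, and 0 on arrays 1, 2 and 3.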
